A study of Mus musculus with 19 samples.

How the data were processed

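Polyadenylated RNA was sequenced from 19 implanted 4T1 tumours. Per the labels, 1000000 tumour cells were implanted in syngeneic BALB/cAnN mice, and treatment with anti-CTLA-4 or control IgG began 3 days later, with 3 doses 3 days apart. Frozen tissue was extracted in TRIzol, and 500 ng of total RNA went through poly(A) selection, a stranded TruSeq kit with 8 cycles of PCR, and paired-end sequencing on a HiSeq instrument. The stated averages were 51 read pairs per sample, in units of 1000000, and 69% mRNA bases. The 4 groups were control tumours with IgG (n = 4), control tumours with anti-CTLA-4 (n = 5), tumours with the LDHA knockdown (LDHA-KD) with IgG (n = 5) and LDHA-KD tumours with anti-CTLA-4 (n = 5). Replicates were numbered, and no label says that each came from a separate animal, so the p-values measure the spread between these samples.

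The deposited values were raw counts per gene from HTSeq 0.5.3 on build mm10, made by the authors without normalization, with 1 column per sample and 5 summary lines for reads that no gene received. Picard 1.124 was also named, without its role. The aligner, the annotation release and the strand setting of the counting were not given in the sources used here. Antisense or overlapping genes, pseudogenes and close paralogs may therefore hold reads of their neighbours or relatives. Gene symbols came with the counts, and coordinates are those of GENCODE M21 on GRCm38, matched by identifier for 46488 of the 46983 genes.

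Total gene counts ran from 31.8 to 43.3 per sample in units of 1000000. CPM is the counts of a gene divided by the scaled library total in units of 1000000. A floor of 3 counts corresponded to between 0.0693 and 0.0944 CPM with the totals before scaling. The floor covers counting error only, because reads without molecular identifiers are not independent molecules. Columns were checked for duplicated libraries within each group, and the lowest chi-square per gene between a pair of libraries was 5.40, so no copy was found within a group. Pairs across groups were not checked.

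Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the group, which left 16763 genes, libraries were scaled with TMM factors, and all 19 samples entered a single model with 1 coefficient per group. Contrasts were tested with edgeR's quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The contrasts were LDHA-KD against control tumours under IgG and under anti-CTLA-4, anti-CTLA-4 against IgG in control and in LDHA-KD tumours, and the interaction, which is the treatment effect in LDHA-KD tumours minus that in control tumours. CPM values are given as mean ± SD. Log2 fold changes come with their standard error (SE).

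Before the data were examined, 33 gene lists with 458 symbols were fixed, of which 3 symbols were absent from the counts. They covered metabolism (glycolysis other than Ldha, hypoxia response, oxidative phosphorylation, TCA cycle, amino acid stress, mitochondrially encoded genes), proliferation, interferon responses and antigen presentation, immune cells, stromal and tumour cells, and tissue that could be carried along (adipocyte, skeletal muscle, skin, lactating mammary gland, erythroid and immediate early genes). Each list was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with an estimated correlation. With the estimate, none of the 33 lists passed in any contrast, and the smallest adjusted p was 0.243, 0.329, 0.272, 0.335 and 0.638 in the order of contrasts above. A two-sided exact permutation test of each list's mean log2 CPM per library was added after seeing the data. It asks whether a list's mean differed between the groups at all, while camera asks whether a list shifted more than the other genes. The smallest possible p of the permutation test was 0.00794. With 33 lists, a list at that value could pass only if other lists also had low p-values. List medians are medians of the members' log2 fold changes computed on log2 CPM (prior count 2), which can differ from edgeR's values given for single genes. The medians had the opposite sign to the test in 2, 4, 1, 1 and 6 lists of the contrasts, and 0 of those lists passed.

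Named genes followed a rule fixed before the data were examined. Ldha, Ldhb, Foxp3, Cd8a, Cd4, Ifng, Gzmb and Ctla4 were given in every contrast. In each comparison of a pair of groups, the 6 largest log2 fold changes in each direction were added among genes past the threshold with a mean log2 CPM of at least 1, at least 90% of library pairs in that direction and a name that is not a predicted-gene name. Up to 6 lists with the smallest camera p gave 3 members each. Further members of lists (such as Eomes, Icos, Xcr1, Epcam, Cldn7, Pgk1, Slc16a1, Pdcd1, Il2ra and Col1a1) are named as examples of their list and were chosen after their values were seen, as was Grem1.

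Alternatives fixed in advance were RLE size factors, no filter, a stricter filter (at least 1 CPM in at least 4 libraries), replicate number as a block, a fit of only the groups compared, DESeq2 1.42.0, limma voom with quality weights, each replicate left out in turn, and the estimated correlation for lists. Thinning to equal depth, leaving out 4 libraries that stood apart on the second principal component, the mean of the lactating mammary gland list as a covariate and the exact permutation of lists were added after seeing the data. The model was tested on simulated data with the same depths and the same spread per gene, in which genes were drawn independently of each other. Of genes changed 2-fold, 80.3% were recovered in the comparison of LDHA-KD with control tumours under IgG, with 12 false calls among 167, and 83.1% in the comparison of anti-CTLA-4 with IgG in LDHA-KD tumours, with 13 false among 184. At 1.5-fold the shares were 47.0% and 55.2%. Variation shared between genes, as on the second principal component, was not simulated, so these shares are not the power in the real samples. No sample and no column was left out of the comparisons.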

Results

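Gene expression was measured in 19 tumours grown from 4T1 cells, a mouse mammary carcinoma line, in BALB/cAnN mice. The series asks how gene expression in control and LDHA-deficient tumours responds to blockade of CTLA-4, an inhibitory receptor of T cells, and its title names regulatory T cell stability in tumours with low glycolysis. Control tumours with IgG had 4 samples (replicates 1, 3, 4 and 5), and the other 3 groups had 5 each. In units of 1000000, gene counts averaged 36.9 ± 2.87 (SD, n = 4) in control tumours with IgG and 38.7 ± 3.14 (n = 5) with anti-CTLA-4. In LDHA-KD tumours they averaged 34.7 ± 2.79 (n = 5) with IgG and 38.7 ± 2.95 (n = 5) with anti-CTLA-4. Between 21934 and 23143 genes had counts in a sample. Of all records, 8.42% to 13.8% fell outside genes and 10.2% to 14.1% did not align uniquely. The first principal component held 41.8% of the variance and separated LDHA-KD from control tumours. The second held 17.0%, and on it LDHA-KD anti-CTLA-4 replicates 3 and 5 and control anti-CTLA-4 replicates 3 and 5 lay apart from the rest. Those LDHA-KD libraries had the highest shares of records outside genes, 13.8% and 12.1%, while those control libraries had 10.3% and 9.70%.

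Ldha, the lactate dehydrogenase subunit targeted by the knockdown (chromosome 7, 46841475 to 46855627, plus strand), was lower in every LDHA-KD sample than in every control sample. Its level was 1926, 1624, 1567 and 1283 CPM in control tumours with IgG and 2244, 1524, 1955, 1910 and 1935 CPM in control tumours with anti-CTLA-4. The LDHA-KD tumours had 478, 470, 452, 506 and 519 CPM with IgG and 566, 485, 584, 525 and 545 CPM with anti-CTLA-4. The log2 fold change of LDHA-KD against control was -1.72 (SE 0.11, adjusted p = 2.46e-09) under IgG and -1.82 (SE 0.11, adjusted p = 6.23e-10) under anti-CTLA-4. Ldhb, the other main subunit (chromosome 6, 142490249 to 142507957, minus strand), did not pass in either, with 0.20 (SE 0.20, adjusted p = 0.460) and 0.12 (SE 0.19, adjusted p = 0.644).

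**Figure D1:**
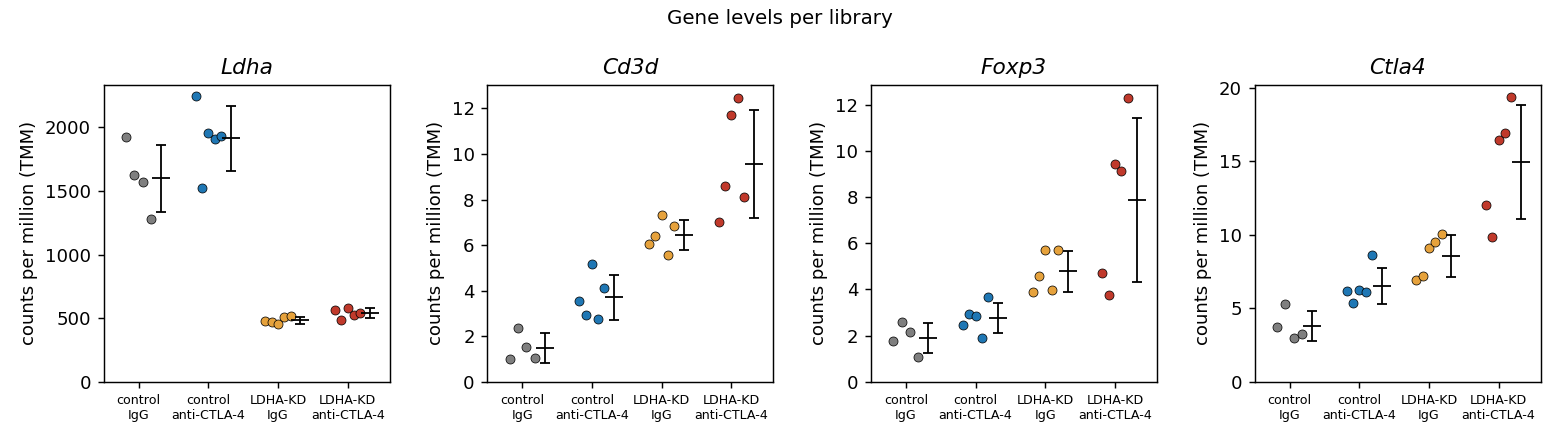
Levels of Ldha, Cd3d, Foxp3 and Ctla4 in CPM for each library (points, in order of replicate number), with mean and SD beside them, in the 4 groups. The LDHA-KD libraries lie between 452 and 584 CPM of Ldha and the control libraries between 1283 and 2244 CPM, while mean Foxp3 runs from 1.89 CPM in control tumours with IgG to 7.87 CPM in LDHA-KD tumours with anti-CTLA-4.

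The comparison of LDHA-KD with control tumours under IgG asks what the knockdown changed without the blockade. T cell genes were higher in LDHA-KD tumours. Cd3d, a chain of the T cell receptor complex (chromosome 9, 44981786 to 44987339), stood at 6.44 ± 0.678 CPM (n = 5) against 1.49 ± 0.644 CPM (n = 4). Its log2 fold change was 2.11 (SE 0.25, adjusted p = 4.18e-06). Cd4, the co-receptor of helper T cells (chromosome 6, 124864692 to 124888221), was higher by 1.91 (SE 0.29), and Cd8a, the co-receptor of cytotoxic T cells (chromosome 6, 71373427 to 71379173), by 2.06 (SE 0.43, adjusted p = 0.00116). Foxp3, the transcription factor that defines regulatory T cells (chromosome X, 7573644 to 7595245), had 4.78 ± 0.896 CPM against 1.89 ± 0.639 CPM, a log2 fold change of 1.33 (SE 0.31, adjusted p = 0.00273). Gzmb, a cytotoxic granule protease (chromosome 14, 56258838 to 56262260), was higher by 1.22 (SE 0.20), and Ctla4 (chromosome 1, 60887000 to 60915832) by 1.16 (SE 0.21, adjusted p = 0.000264). For each of these genes all LDHA-KD samples lay above all control samples. Ifng, the gene of interferon-gamma (chromosome 10, 118441046 to 118445892), had a log2 fold change of 1.04 (SE 0.49) that did not pass (adjusted p = 0.109). Without control anti-CTLA-4 replicate 5, which enters through the shared spread, its adjusted p was 0.0409, and with limma voom it was 0.0239.

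Of the 20 T cell genes measured, 19 were higher in LDHA-KD tumours and 19 when adjusted over the list alone, with a list median of 1.99 on the log2 scale. Lck, a T cell receptor kinase, was higher by 1.53 (SE 0.19) and Sh2d2a, an adaptor of activated T cells, by 2.29 (SE 0.28). The call was lost when the correlation was estimated (adjusted p = 0.278 with an estimated correlation). All 8 natural killer cell genes were higher (8 adjusted over the list alone, median 1.86), among them Ncr1, an activating receptor, by 2.17 (SE 0.37), Xcl1 by 2.16 (SE 0.31) and Klrk1 by 1.83 (SE 0.31). The list had an adjusted p = 0.278 with an estimated correlation. The cytotoxic lymphocyte list (median 1.75) had 11 of 14 members higher and 1 lower, and 13 and 1 adjusted over the list alone. The exception was Eomes, a transcription factor of cytotoxic cells, at -1.27 (SE 0.15). That list had an adjusted p = 0.304 with an estimated correlation. In the regulatory T cell list, 8 of 13 members were higher and 2 lower, and 9 and 2 adjusted over the list alone (median 1.32, adjusted p = 0.428 with an estimated correlation). Tnfrsf18, a costimulatory receptor abundant on these cells, was higher by 1.78 (SE 0.21) and Ccr8, a chemokine receptor of tumour regulatory T cells, by 1.68 (SE 0.28), while Ikzf2 was lower at -0.41 (SE 0.14) and Tnfrsf9 at -0.67 (SE 0.25). In control tumours with IgG, Ikzf2 had 49.9 CPM and Tnfrsf9 86.3 CPM, far above Foxp3, so other cells may hold both. The T cell activation and checkpoint list had 8 of 12 higher (8 higher and 1 lower adjusted over the list alone, median 0.92), with Icos, a costimulatory receptor, at 1.81 (SE 0.26), and an adjusted p = 0.399 with an estimated correlation.

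Other leukocyte genes followed. The mast cell list had 7 of 8 members higher and 7 adjusted over the list alone (median 1.93, adjusted p = 0.243 with an estimated correlation), led by the mast cell proteases Tpsab1 at 2.76 (SE 0.21), Tpsb2 at 2.48 (SE 0.23) and Mcpt4 at 1.78 (SE 0.20). Macrophage genes were higher in 12 of 15 cases and in 14 adjusted over the list alone (median 0.95, adjusted p = 0.243 with an estimated correlation). Trem2, a lipid-sensing receptor, was higher by 0.93 (SE 0.11), the complement gene C1qa by 1.16 (SE 0.18) and the lipid carrier gene Apoe by 1.29 (SE 0.20). All 9 genes of MHC class II presentation were higher, also adjusted over the list alone (median 1.52, adjusted p = 0.304 with an estimated correlation), with H2-DMa at 1.33 (SE 0.19), H2-Aa at 1.66 (SE 0.27) and H2-Eb1 at 1.78 (SE 0.29). Dendritic cell genes were higher in 7 of 11 cases and lower in 1 (the same counts adjusted over the list alone, median 1.22, adjusted p = 0.428 with an estimated correlation), and Xcr1, a receptor of cross-presenting dendritic cells, was higher by 2.13 (SE 0.34). B cell genes were higher in 5 of 9 cases (6 adjusted over the list alone, median 1.23, adjusted p = 0.278 with an estimated correlation). The interferon-gamma response list had 6 of 22 members higher and 6 adjusted over the list alone (median 0.48, adjusted p = 0.633 with an estimated correlation), and without control IgG replicate 4 its median was 0.28 and its adjusted p was 0.0911 with the preset correlation. The MHC class I presentation list had 4 of 12 higher and 5 adjusted over the list alone (median 0.35, adjusted p = 0.633 with an estimated correlation), and it lost the call without control IgG replicate 4 (median 0.19), control IgG replicate 5 (median 0.29) or LDHA-KD IgG replicate 2 (median 0.34). The eosinophil list stood at the edge of the threshold (median 1.53, adjusted p = 0.617 with an estimated correlation), with 2 of 6 members higher and 4 adjusted over the list alone, and its call was lost with 11 of the 19 libraries left out in turn, its median lowest at 1.09 without control IgG replicate 1.

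Genes of the hypoxia response were lower in LDHA-KD tumours in 14 of 21 cases and in 16 adjusted over the list alone (median -0.52, adjusted p = 0.515 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling, had -1.12 (SE 0.13), Adm, the adrenomedullin gene, -1.59 (SE 0.32) and Vegfa, the angiogenic growth factor, -1.06 (SE 0.28). Proliferation genes were lower in 17 of 25 cases and in 18 adjusted over the list alone (median -0.39, adjusted p = 0.428 with an estimated correlation). The replication helicase genes Mcm7 and Mcm3 had -0.46 (SE 0.08) and -0.45 (SE 0.10), and Tpx2, a spindle assembly factor, -0.43 (SE 0.09). The endothelial list had 9 of 12 members lower and 1 higher, also adjusted over the list alone (median -0.60, adjusted p = 0.278 with an estimated correlation), with Emcn at -1.27 (SE 0.13), Cdh5, the endothelial cadherin, at -0.80 (SE 0.14) and Eng higher at 0.54 (SE 0.12). The epithelial tumour cell list had 4 of 11 lower and 1 higher, also adjusted over the list alone (median -0.30, adjusted p = 0.278 with an estimated correlation). Epcam, an epithelial adhesion molecule, had -2.19 (SE 0.18) and Cldn7, a tight junction gene, 1.38 (SE 0.10). The amino acid stress (ATF4) response list had 7 of 15 lower, also adjusted over the list alone (median -0.37, adjusted p = 0.617 with an estimated correlation), and lost the call without LDHA-KD IgG replicate 1 (median -0.35), LDHA-KD IgG replicate 2 (-0.31) or control IgG replicate 3 (-0.34).

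The remaining 15 lists did not pass with camera. Glycolysis other than Ldha had 1 member higher and 4 lower, also adjusted over the list alone (median -0.11). Pgk1, a glycolytic kinase, was lower at -0.56 (SE 0.14) and Slc16a1, a lactate transporter, was higher at 0.64 (SE 0.13). Medians were -0.11 for oxidative phosphorylation, -0.12 for the TCA cycle, -0.40 for fibroblast and matrix, -0.49 for erythroid, -0.11 for keratinocyte and skin, -0.01 for skeletal muscle and -0.03 for mitochondrially encoded genes. They were 1.31 for plasma cell, 0.33 for neutrophil, 0.24 for adipocyte, 0.86 for lactating mammary gland, 0.07 for helper T cell cytokines, 0.08 for immediate early and 0.00 for type I interferon response genes.

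The largest changes under IgG were in genes outside the lists, except Cldn4, a member of the epithelial tumour cell list. Rps6-ps1, annotated as a processed pseudogene (chromosome 15, 76337616 to 76338362), had 27.3 ± 3.21 CPM against 0.319 ± 0.0673 CPM, a log2 fold change of 6.40 (SE 0.22). Reads of its parent gene cannot be separated from its own here. Gnao1, a G protein subunit gene (chromosome 8), was higher by 4.08 (SE 0.30), Nptx1, a neuronal pentraxin gene (chromosome 11), by 4.01 (SE 0.28), Mrgprb1 by 3.61 (SE 0.46), Tnip3 by 3.56 (SE 0.16) and Ibsp, a bone sialoprotein gene (chromosome 5), by 3.48 (SE 0.26). Lama3, a laminin chain of epithelial basement membrane (chromosome 18, 12333819 to 12583013), had 44.2 ± 4.62 CPM against 412 ± 112 CPM, a log2 fold change of -3.22 (SE 0.21). Fgfbp1 had -3.00 (SE 0.24), the tight junction gene Cldn4 -2.80 (SE 0.17), Rspo3 -2.74 (SE 0.33), Myo5b -2.69 (SE 0.19) and Rps6ka6 -2.67 (SE 0.30). For each of the 12 genes all LDHA-KD samples lay on the same side of all control samples.

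In total 2814 genes were higher and 2938 lower in LDHA-KD tumours under IgG with edgeR's quasi-likelihood test, 858 and 612 of them by more than 2-fold, and 7348 genes had an unadjusted p under 0.05. Camera with the preset correlation called 13 lists higher and 5 lower. The exact permutation test of list means does not rest on a preset correlation. Unlike camera, it asks whether a list differed at all, in a contrast where 34.3% of all genes were called. It called 19 lists, with a smallest adjusted p of 0.0175, which is not a repeat of camera's result by other means. They were not the same lists. The exact test did not call the amino acid stress (ATF4) response and eosinophil lists (adjusted p = 0.0748 for each), and it called the TCA cycle and plasma cell lists (adjusted p = 0.0175 for each) and the fibroblast and matrix list (adjusted p = 0.0291), which camera did not.

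**Figure D2:**
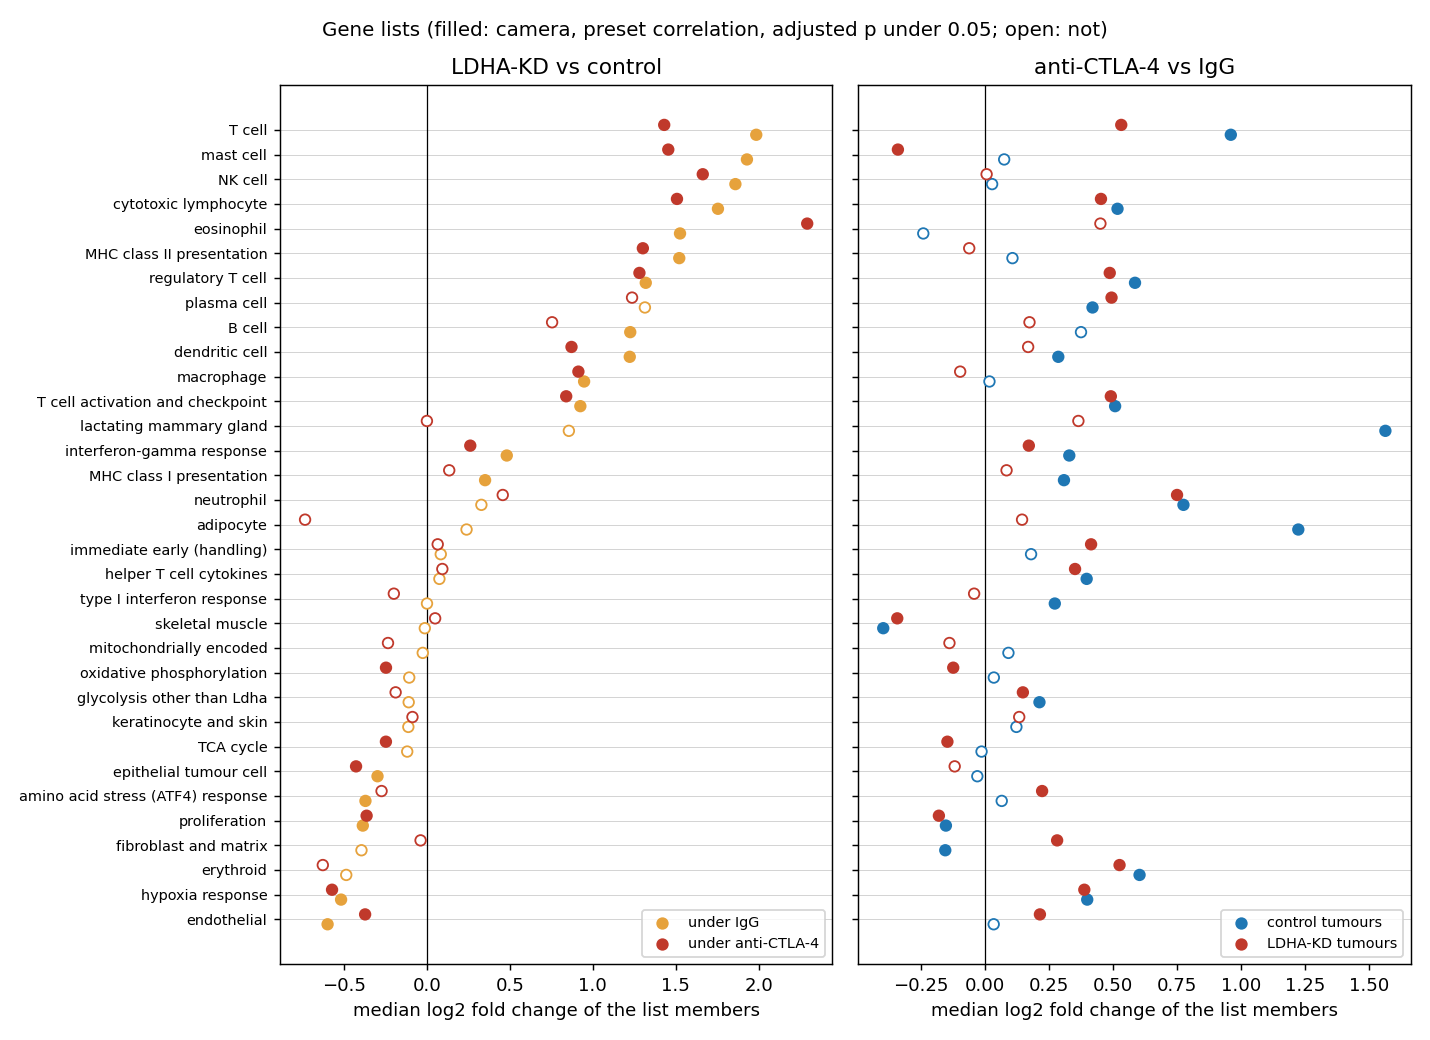
Median log2 fold change of the members of each of the 33 gene lists, for LDHA-KD against control tumours (left) and for anti-CTLA-4 against IgG (right); filled points passed camera with the preset correlation. The T cell list has 1.99 under IgG and 1.43 under anti-CTLA-4 on the left, and 0.96 in control and 0.53 in LDHA-KD tumours on the right, and no list passed with an estimated correlation.

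Under anti-CTLA-4, LDHA-KD and control tumours differed in much the same genes. Cd4 was higher by 1.48 (SE 0.26), Cd8a by 2.09 (SE 0.39, adjusted p = 0.000342), Gzmb by 1.41 (SE 0.18), Ctla4 by 1.20 (SE 0.19) and Foxp3 by 1.51 (SE 0.28, adjusted p = 0.000370), with 7.87 ± 3.55 CPM of Foxp3 (n = 5) against 2.76 ± 0.656 CPM (n = 5). Of the library pairs, 88.0% had more Cd8a in the LDHA-KD sample and all had more Foxp3. Ifng had 0.91 (SE 0.43, adjusted p = 0.0964). It passed without control anti-CTLA-4 replicate 5, at 1.58 (adjusted p = 0.00283), and without LDHA-KD anti-CTLA-4 replicate 2, at 1.11 (adjusted p = 0.0416).

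All 20 T cell genes were higher, also adjusted over the list alone (median 1.43, adjusted p = 0.348 with an estimated correlation), among them Sh2d2a by 2.03 (SE 0.25), Cd247 by 1.50 (SE 0.20) and Ubash3a by 1.91 (SE 0.27). All 8 natural killer cell genes (median 1.66), all 8 mast cell genes (median 1.45) and all 9 MHC class II genes (median 1.30) were higher, also adjusted over the list alone, each with an adjusted p = 0.348 with an estimated correlation. Xcl1 was higher by 2.07 (SE 0.28), Klre1 by 1.89 (SE 0.30) and Klra7 by 2.48 (SE 0.42). Tpsab1 had 2.28 (SE 0.19), Tpsb2 1.92 (SE 0.20) and Mcpt4 1.46 (SE 0.18). Cd74, the invariant chain of class II molecules, was higher by 1.53 (SE 0.25), H2-DMa by 1.30 (SE 0.17) and H2-DMb2 by 1.28 (SE 0.21). The regulatory T cell list had 9 of 13 higher, and 9 higher and 1 lower adjusted over the list alone (median 1.28, adjusted p = 0.348 with an estimated correlation), and the cytotoxic lymphocyte list 11 of 14 higher and 1 lower, and 12 and 1 adjusted over the list alone (median 1.51, adjusted p = 0.348 with an estimated correlation). Macrophage genes were higher in 14 of 15 cases, also adjusted over the list alone (median 0.91, adjusted p = 0.329 with an estimated correlation), with Trem2 at 0.87 (SE 0.11), Csf1r, the receptor of macrophage growth factor, at 1.05 (SE 0.15) and Fcgr1 at 0.97 (SE 0.16). Dendritic cell genes were higher in 9 of 11 cases and lower in 1, also adjusted over the list alone (median 0.87, adjusted p = 0.355 with an estimated correlation), and T cell activation and checkpoint genes were higher in 9 of 12 cases, also adjusted over the list alone (median 0.84, adjusted p = 0.348 with an estimated correlation). Eosinophil genes were higher in 5 of 6 cases, also adjusted over the list alone (median 2.29, adjusted p = 0.451 with an estimated correlation).

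Proliferation genes were lower in 19 of 25 cases and in 22 adjusted over the list alone (median -0.36, adjusted p = 0.348 with an estimated correlation), with the mitotic kinase gene Aurka at -0.65 (SE 0.09), Birc5, a survival and mitosis gene, at -0.74 (SE 0.11) and Mcm7 at -0.57 (SE 0.08). The hypoxia response list had 13 of 21 lower and 15 adjusted over the list alone (median -0.57, adjusted p = 0.467 with an estimated correlation). Oxidative phosphorylation had 14 of 24 lower and 16 adjusted over the list alone (median -0.25, adjusted p = 0.467 with an estimated correlation). The TCA cycle list had 7 of 14 lower and 8 adjusted over the list alone (median -0.25, adjusted p = 0.348 with an estimated correlation), and the endothelial list 6 of 12 lower and 1 higher, also adjusted over the list alone (median -0.37, adjusted p = 0.355 with an estimated correlation). The epithelial tumour cell list had 7 of 11 lower and 1 higher, also adjusted over the list alone (median -0.43, adjusted p = 0.348 with an estimated correlation). Among the genes taken for the size of their change were Rps6-ps1 at 5.80 (SE 0.19), Gnao1 at 4.13 (SE 0.28), Ibsp at 3.67 (SE 0.24), Tnip3 at 3.64 (SE 0.15), Mrgprb1 at 3.41 (SE 0.43) and Tnfrsf19 at 3.32 (SE 0.29). In the other direction were Lama3 at -3.29 (SE 0.21), Rspo3 at -3.20 (SE 0.32), Fgfbp1 at -3.15 (SE 0.24), Cldn4 at -2.94 (SE 0.16), Rps6ka6 at -2.85 (SE 0.30) and Wnt10b at -2.64 (SE 0.23).

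With edgeR's quasi-likelihood test, 3390 genes were higher and 3321 lower under anti-CTLA-4, 887 and 511 of them by more than 2-fold, and 8197 had an unadjusted p under 0.05. Without the 4 libraries apart on the second component, an alternative chosen after seeing the data, 2131 were higher and 2177 lower. Camera called 11 lists higher and 6 lower with the preset correlation, and the exact permutation test of list means called 18, with a smallest adjusted p of 0.0201. The exact test did not call oxidative phosphorylation (adjusted p = 0.0965) or the interferon-gamma response (adjusted p = 0.262). It called the B cell and plasma cell lists (adjusted p = 0.0201 for each) and the erythroid list (adjusted p = 0.0308), which camera did not. The interferon-gamma response list was among those camera called (median 0.26, adjusted p = 0.767 with an estimated correlation), and its median was 0.08 (adjusted p = 0.0860 with the preset correlation) without those 4 libraries and 0.09 without control anti-CTLA-4 replicate 3. The call was also lost without control anti-CTLA-4 replicate 4 (0.24), LDHA-KD anti-CTLA-4 replicate 1 (0.27) or LDHA-KD anti-CTLA-4 replicate 3 (0.14).

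Across the 16763 genes, the log2 fold changes of LDHA-KD against control under IgG and under anti-CTLA-4 had a Pearson r of 0.854 and a Spearman rho of 0.831, and 84.6% of genes had the same sign. Genes are not independent replicates, so these are given without a p. Both contrasts called 2376 genes higher, against 569 expected from the separate counts, and 2351 lower, against 582 expected, and 0 genes were called in opposite directions. Any fixed difference between the cell populations enters both contrasts, so the overlap does not single out the knockdown.

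**Figure D3:**
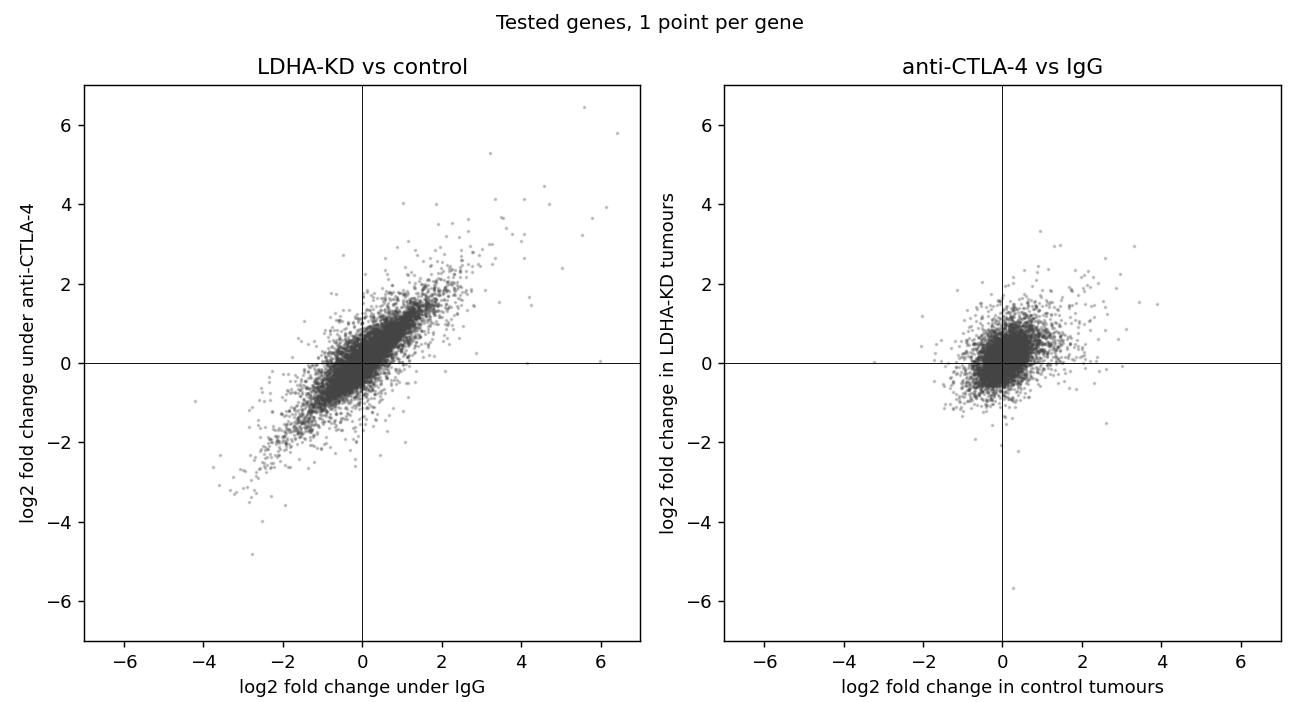
Log2 fold change of each tested gene for LDHA-KD against control under IgG and under anti-CTLA-4 (left) and for anti-CTLA-4 against IgG in control and in LDHA-KD tumours (right), 1 point per gene. Pearson r across genes is 0.854 on the left and 0.465 on the right.

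In control tumours, the comparison of anti-CTLA-4 with IgG asks what the blockade changed where Ldha was intact. No single gene passed the threshold, and T cell genes had the smallest camera p of the 33 lists. Cd3d stood at 3.71 ± 0.988 CPM (n = 5) with anti-CTLA-4 against 1.49 ± 0.644 CPM (n = 4) with IgG, a log2 fold change of 1.32 (SE 0.25, adjusted p = 0.385 over all genes with edgeR), and every treated sample lay above every IgG sample. Trbc2, a constant segment of the T cell receptor, had 1.47 (SE 0.28), Lck 0.83 (SE 0.19) and Cd4 1.07 (SE 0.29). Over all genes 0 of the 20 T cell genes passed, and 18 were higher when adjusted over the list alone (median 0.96, adjusted p = 0.272 with an estimated correlation). Foxp3 had 0.54 (SE 0.31, adjusted p = 0.653), Ctla4 0.77 (SE 0.21, adjusted p = 0.601), Cd8a 0.40 (SE 0.44), Gzmb 0.43 (SE 0.19), Ifng 0.83 (SE 0.49), Ldha 0.26 (SE 0.11) and Ldhb -0.06 (SE 0.20). None of these passed. Without control anti-CTLA-4 replicate 5, which had 2.81 CPM of Ifng against 0.311 to 1.10 CPM in the other 4, Ifng was 0.17.

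The regulatory T cell list passed camera with 0 of 13 members past the threshold over all genes and 4 higher adjusted over the list alone (median 0.59, adjusted p = 0.272 with an estimated correlation), and its examples were Tnfrsf18 at 0.83 (SE 0.21) and Tnfrsf9 at 0.83 (SE 0.26). Tnfrsf9 had 86.3 CPM with IgG and 154 CPM with anti-CTLA-4, while no control library exceeded 3.68 CPM of Foxp3. Its change therefore cannot be assigned to regulatory T cells. Hypoxia response (median 0.40) and glycolysis other than Ldha (median 0.21) passed with 0 members past the threshold over all genes or over the list alone, each with an adjusted p = 0.272 with an estimated correlation. Ero1l had 0.82 (SE 0.27), Egln1 0.40 (SE 0.14), Ndrg1 0.60 (SE 0.22), Pgam1 0.30 (SE 0.12), the glucose transporter gene Slc2a1 0.63 (SE 0.26) and Gapdh 0.26 (SE 0.11). The neutrophil list had 0 of 15 over all genes and 4 higher adjusted over the list alone (median 0.78, adjusted p = 0.272 with an estimated correlation), with the alarmin genes S100a9 at 1.08 (SE 0.33) and S100a8 at 0.98 (SE 0.32) and the lectin gene Clec4d at 0.87 (SE 0.28). Type I interferon response passed with 0 of 20 over all genes or over the list alone (median 0.27, adjusted p = 0.372 with an estimated correlation).

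The cytotoxic lymphocyte (median 0.52), T cell activation and checkpoint (median 0.51, 2 members higher adjusted over the list alone) and erythroid (median 0.60) lists passed camera as higher, each with an adjusted p = 0.272 with an estimated correlation. MHC class I presentation passed at 0.31 (adjusted p = 0.372 with an estimated correlation) and proliferation at -0.15 (adjusted p = 0.402 with an estimated correlation). Other calls were lost without a single library. They were those of the interferon-gamma response list (median 0.33, and 0.06 without control IgG replicate 4 or 0.09 without control anti-CTLA-4 replicate 5), the plasma cell list (0.42, and 0.25 without control IgG replicate 1), the helper T cell cytokines list (0.40, and 0.37 without control IgG replicate 4) and the skeletal muscle list (-0.40, and -0.14 without control anti-CTLA-4 replicate 5). The dendritic cell list (0.29) lost its call without control IgG replicate 1 (0.15) or 4 (0.33) or control anti-CTLA-4 replicate 2 (0.30), 3 (0.22) or 5 (0.15), and the fibroblast and matrix list (-0.16) without control IgG replicate 3 (-0.14) or 4 (-0.12) or control anti-CTLA-4 replicate 1 (-0.10) or 4 (-0.15). With an estimated correlation their adjusted p lay between 0.272 and 0.491, and 0 of their members passed over all genes.

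Markers of fat and of the mammary gland shifted in the same samples. The adipocyte list had 0 of 10 over all genes and 9 higher adjusted over the list alone (median 1.22, adjusted p = 0.272 with an estimated correlation), with the fat cell genes Fabp4 at 1.39 (SE 0.44), Lep at 2.38 (SE 0.79) and Plin1 at 2.07 (SE 0.71). Fabp4 was 180 ± 162 CPM with anti-CTLA-4 against 68.8 ± 23.2 CPM with IgG. Without control anti-CTLA-4 replicate 5 the adipocyte median was 0.66, and without the 4 libraries apart on the second component it was 0.29 and did not pass (adjusted p = 0.0839 with the preset correlation). The lactating mammary gland list had 4 of 6 higher adjusted over the list alone and 0 over all genes (median 1.57, adjusted p = 0.372 with an estimated correlation), and without those 4 libraries 0.49 (adjusted p = 0.248 with the preset correlation). The T cell, regulatory T cell, hypoxia response and neutrophil medians without them were 0.68, 0.50, 0.33 and 0.42, each still past the threshold with the preset correlation.

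For anti-CTLA-4 in control tumours, edgeR's quasi-likelihood test called 0 genes, with 1346 at an unadjusted p under 0.05 and 838 expected by chance. The 1346 rested in part on single libraries. It was 713 without control IgG replicate 5, and 745 and 851 without control anti-CTLA-4 replicates 5 and 1. It was 2193 without control IgG replicate 1 and 2203 without control anti-CTLA-4 replicate 2. It was 536 with the mammary gland covariate and 467 without the 4 libraries apart on the second component. DESeq2 called 11 genes higher and 2 lower, and limma voom with quality weights called 0. The genes DESeq2 called higher included Cd3d, Trbc2, Lck, Cd3g, Cd2, Zap70 and Icos, and Cd3d had the log2 fold change 1.32 (adjusted p = 0.000791 with DESeq2). Camera with the preset correlation called 16 lists higher and 3 lower. The exact permutation test called 0, with a smallest adjusted p of 0.262. Since that test cannot pass a list on its own with these samples, its 0 calls do not show that no list shifted.

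**Figure D4:**
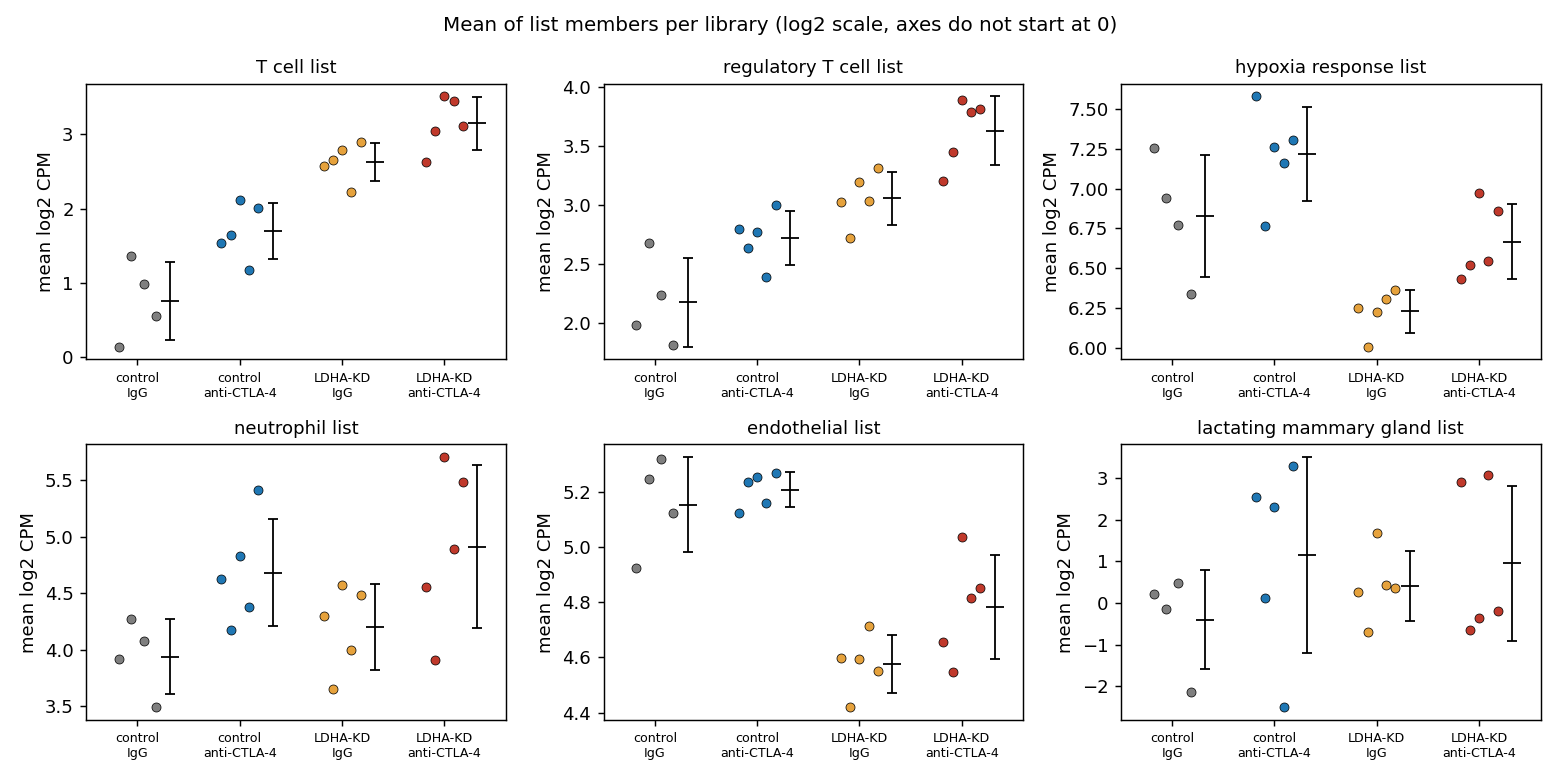
Mean log2 CPM of the members of 6 gene lists for each library (points, in order of replicate number), with mean and SD beside them, in the 4 groups. The T cell mean runs from 0.14 in control IgG replicate 1 to 3.51 in LDHA-KD anti-CTLA-4 replicate 3, and the lactating mammary gland mean varies widely within both anti-CTLA-4 groups, from -2.51 to 3.29 in control tumours.

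In LDHA-KD tumours, the comparison of anti-CTLA-4 with IgG asks what the blockade changed where Ldha was lowered, and regulatory T cell genes bear on the question in the series title. No single gene passed. Foxp3 was 7.87 ± 3.55 CPM (n = 5) with anti-CTLA-4 and 4.78 ± 0.896 CPM (n = 5) with IgG, a log2 fold change of 0.72 (SE 0.28, adjusted p = 0.337 with edgeR), and 72.0% of library pairs had more Foxp3 in the treated sample. The treated samples had 4.70, 3.78, 9.45, 9.14 and 12.3 CPM of Foxp3 in replicates 1 to 5. Without the 4 libraries apart on the second component, which include replicates 3 and 5, the log2 fold change of Foxp3 was 0.30 and that of Cd8a 0.023. With limma voom Foxp3 passed at 0.79 (adjusted p = 0.0224), and with DESeq2 it did not (adjusted p = 0.215). In limma voom LDHA-KD anti-CTLA-4 replicate 4 had a quality weight of 3.45 against 0.467 to 0.694 in the other 4 treated samples. Ctla4 had 0.80 (SE 0.19, adjusted p = 0.293), the interleukin-2 receptor gene Il2ra 0.74 (SE 0.24) and Tnfrsf9 0.90 (SE 0.24). Tnfrsf9 had 54.4 CPM with IgG and 102 CPM with anti-CTLA-4, far above Foxp3, so its change cannot be assigned to regulatory T cells. The regulatory T cell list had 0 of 13 members past the threshold over all genes and 6 higher adjusted over the list alone (median 0.49, adjusted p = 0.335 with an estimated correlation), and all 13 had a positive log2 fold change. Cd4 had 0.64 (SE 0.25), Cd8a 0.43 (SE 0.36), Gzmb 0.62 (SE 0.18, adjusted p = 0.295), Ifng 0.70 (SE 0.42), Ldha 0.16 (SE 0.10) and Ldhb -0.15 (SE 0.19). None passed.

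Among T cell genes, all 20 had a positive log2 fold change and 0 passed over all genes or over the list alone (median 0.53, adjusted p = 0.343 with an estimated correlation). Cd3g had 0.68 (SE 0.23), Zap70 0.62 (SE 0.23) and Cd3d 0.57 (SE 0.22). The T cell activation and checkpoint list had 5 of 12 higher adjusted over the list alone and 0 over all genes (median 0.49, adjusted p = 0.335 with an estimated correlation), with Pdcd1, the PD-1 gene, at 0.66 (SE 0.22) and Icos at 0.77 (SE 0.23). Hypoxia response genes had 0 of 21 over all genes and 9 higher adjusted over the list alone (median 0.39, adjusted p = 0.335 with an estimated correlation), with Stc2, a stress-induced glycoprotein gene, at 1.39 (SE 0.30), Ak4 at 0.70 (SE 0.17) and P4ha2, a collagen hydroxylase gene, at 0.64 (SE 0.18). The neutrophil list had 0 of 15 over all genes and 9 adjusted over the list alone (median 0.75, adjusted p = 0.335 with an estimated correlation), with Clec4e at 0.94 (SE 0.27), Mmp9 at 1.06 (SE 0.31) and Clec4d at 0.84 (SE 0.26). Proliferation genes had 0 over all genes and 1 lower adjusted over the list alone (median -0.18, adjusted p = 0.343 with an estimated correlation), with Mcm7 at -0.30 (SE 0.08), Aurka at -0.24 (SE 0.09) and Mcm6 at -0.24 (SE 0.09). Oxidative phosphorylation had 0 over all genes or over the list alone (median -0.12, adjusted p = 0.433 with an estimated correlation), with Ndufv1 at -0.22 (SE 0.08), Sdhb at -0.22 (SE 0.09) and Atp5o at -0.18 (SE 0.09).

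In LDHA-KD tumours no shift of mammary gland genes passed over all libraries. The lactating mammary gland list had a median of 0.37 with all 6 members positive and did not pass (adjusted p = 0.245 with the preset correlation), with 0 members past the threshold over all genes or over the list alone. The milk protein gene Csn3 had 1.57 (SE 0.66), from 6.59 to 19.5 CPM. Outside the list, and chosen after their values were seen, Prlr, the prolactin receptor gene, had 2.21 (SE 0.74), from 1.92 to 8.80 CPM, and Wfdc18 had 1.87 (SE 0.61), from 1.57 to 5.75 CPM. None of these genes passed. Without the 4 libraries apart on the second component Csn3, Prlr and Wfdc18 were 1.75, 1.30 and 1.89 and did not pass. The list was then 1.33 and passed (adjusted p = 0.00137 with the preset correlation), on 3 treated samples with list means of 2.92, -0.65 and 3.07. The adipocyte list had a median of 0.15 and did not pass.

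Camera also called lists of other cells and states, with 0 members past the threshold over all genes. Immediate early genes had a median of 0.41 (5 higher adjusted over the list alone) and fibroblast and matrix genes 0.28, each with an adjusted p = 0.349 with an estimated correlation. Endothelial genes had 0.21, plasma cell genes 0.49 (1 adjusted over the list alone) and helper T cell cytokines 0.35 (2 adjusted over the list alone), each with an adjusted p = 0.335 with an estimated correlation. Cytotoxic lymphocyte genes had 0.45 and amino acid stress genes 0.22 (1 each adjusted over the list alone), with an adjusted p = 0.378 with an estimated correlation, and glycolysis other than Ldha 0.15, with an adjusted p = 0.438 with an estimated correlation. The TCA cycle list had -0.15 (adjusted p = 0.349 with an estimated correlation). The erythroid list (0.53) lost its call without LDHA-KD IgG replicate 4 (0.35) and the skeletal muscle list (-0.34) without LDHA-KD IgG replicate 1 (-0.19), with an adjusted p = 0.378 and 0.445 with an estimated correlation. The mast cell list (-0.34, adjusted p = 0.526 with an estimated correlation) lost its call with 13 of the 19 libraries left out in turn. The interferon-gamma response list (0.17, adjusted p = 0.727 with an estimated correlation) lost its call without LDHA-KD anti-CTLA-4 replicate 1 (0.18), 3 (0.06) or 4 (0.16) or LDHA-KD IgG replicate 3 (0.10) or 4 (0.14).

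Without the 4 libraries apart on the second component, the calls of the immediate early (0.07), fibroblast and matrix (0.07), helper T cell cytokines (0.04), cytotoxic lymphocyte (0.10), amino acid stress (ATF4) response (0.07), glycolysis other than Ldha (0.06) and TCA cycle (-0.01) lists were lost. The T cell, regulatory T cell, hypoxia response and neutrophil medians in LDHA-KD tumours were 0.40, 0.38, 0.22 and 0.29, each still past the threshold with the preset correlation, while the oxidative phosphorylation median was 0.01 (adjusted p = 0.988) and did not pass. The edgeR test called 0 genes for anti-CTLA-4 in LDHA-KD tumours, with 1987 at an unadjusted p under 0.05 and 838 expected by chance. The 1987 became 919, 1158 and 3391 without LDHA-KD anti-CTLA-4 replicates 3, 5 and 1, and 368 without the 4 libraries. Without LDHA-KD anti-CTLA-4 replicate 1 it called 1 gene, Grem1, an inhibitor of bone morphogenetic proteins, at 0.86. DESeq2 called 43 genes higher and 6 lower, Ctla4 among the former with 0.80 (adjusted p = 0.0245 with DESeq2), and limma voom, with the uneven quality weights above, called 930 higher and 549 lower. Camera called 15 lists higher and 5 lower with the preset correlation. The exact permutation test of list means called 0, with a smallest adjusted p of 0.175. Its smallest unadjusted p was 0.00794, the lowest it can give, so these 0 calls do not show that no list shifted.

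The interaction asks whether the blockade acted differently in LDHA-KD and control tumours. Foxp3 differed by 0.18 (SE 0.42), Cd8a by 0.03 (SE 0.59), Cd4 by -0.43 (SE 0.38), Ifng by -0.13 (SE 0.64), Gzmb by 0.19 (SE 0.26), Ctla4 by 0.04 (SE 0.28), Ldha by -0.10 (SE 0.15) and Ldhb by -0.09 (SE 0.27) on the log2 scale. None passed. The edgeR test called 0 genes, with 415 at an unadjusted p under 0.05 against 838 expected by chance, and DESeq2 and limma voom with quality weights also called 0, with 571 and 3087 at an unadjusted p under 0.05. The 415 became 1096 and 266 without LDHA-KD anti-CTLA-4 replicates 1 and 3. It became 1028 without control IgG replicate 1, 691 without control anti-CTLA-4 replicate 2 and 160 without the 4 libraries. Standard errors of this size leave differences of the order of the treatment effects themselves undetected.

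At the level of lists, camera with the preset correlation called 2 higher and 8 lower in the interaction. Fibroblast and matrix genes had a median of 0.36 with 14 of 14 members positive, and the collagen genes Col1a1 and Col1a2 had 0.79 (SE 0.36) and 0.79 (SE 0.33). Type I interferon response genes had a median of -0.33. Oxidative phosphorylation had -0.17 and T cell genes -0.43, the last with 18 of 20 members negative. Every list had 0 members past the threshold over all genes and over the list alone, and the adjusted p was 0.638 with an estimated correlation for fibroblast and matrix and 0.692 with an estimated correlation for the other 3. The T cell list did not pass without control IgG replicate 1, at -0.26 (adjusted p = 0.101 with the preset correlation), and oxidative phosphorylation did not pass without the 4 libraries apart on the second component, at -0.04.

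Log2 fold changes of anti-CTLA-4 in control and in LDHA-KD tumours, which share no library, had a Pearson r of 0.465 and a Spearman rho of 0.441 across genes, and 66.7% of genes had the same sign. The arms may still share structure by replicate number. With group means removed, libraries of different groups had a median correlation of 0.116 with the same number and -0.042 with different numbers. Of the 19 libraries, 5 correlated best with their own number. With limma voom r was 0.273, and without the 4 libraries apart on the second component it was 0.248.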

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

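The regional test of gene counts was chosen before its result was seen, and the tests on thinned counts, endothelial genes, B cell genes, mammary gland genes, the 4 libraries apart on the second component and other splits of the samples were chosen only after the results were seen. Of 452 sets of values within a group, 18 had a sample far from the others, where chance gives 22.6. LDHA-KD anti-CTLA-4 replicate 2 and control IgG replicate 5 held 4 each, and each other library held 2 or fewer.

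Among genes, Ifng was 0.298 CPM in control IgG replicate 4, below the others of its group, and Ctla4 was 8.63 CPM in control anti-CTLA-4 replicate 5, above the others. Tnfrsf19 was 3.31 CPM, S100a9 144 CPM and Fabp4 103 CPM in control IgG replicate 5. Csf1r was 95.3 CPM in control IgG replicate 1, Aurka 60.7 CPM in control anti-CTLA-4 replicate 3 and Atp5o 135 CPM in control anti-CTLA-4 replicate 2. Ero1l was 151 CPM in LDHA-KD IgG replicate 2 and P4ha2 22.3 CPM in LDHA-KD IgG replicate 3. H2-DMb2 was 9.59 CPM and Fabp4 42.3 CPM in LDHA-KD anti-CTLA-4 replicate 2. Among list means on the log2 scale, the TCA cycle was 7.08 in control anti-CTLA-4 replicate 4, proliferation 6.93 in LDHA-KD IgG replicate 3, MHC class I presentation 7.99 and MHC class II presentation 4.63 in LDHA-KD anti-CTLA-4 replicate 2, and immediate early genes 4.94 in control IgG replicate 5 and 5.0 in LDHA-KD IgG replicate 2.

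For 10 lists, camera with the preset correlation called the treatment effect different between LDHA-KD and control tumours, and none passed with an estimated correlation. The median difference was 0.36 for fibroblast and matrix and 0.12 for endothelial genes. It was -0.33 for type I interferon response, -0.17 for oxidative phosphorylation, -0.43 for T cell, -1.11 for adipocyte, -0.10 for TCA cycle, -0.39 for mast cell, -0.22 for MHC class I presentation and -0.23 for mitochondrially encoded genes. Single libraries ended some of these calls. The T cell median was -0.26 without control IgG replicate 1, the adipocyte median -0.48 without control anti-CTLA-4 replicate 5, the TCA cycle median -0.06 without LDHA-KD anti-CTLA-4 replicate 3, and the mast cell median -0.28 without control IgG replicate 1 and -0.35 without control anti-CTLA-4 replicate 5. MHC class I presentation ended without LDHA-KD anti-CTLA-4 replicate 2 (-0.11), control anti-CTLA-4 replicate 5 (-0.15), control IgG replicate 4 (-0.09) or 5 (-0.14). The endothelial call ended without LDHA-KD anti-CTLA-4 replicate 3 (0.10), LDHA-KD IgG replicate 2 (0.08), control anti-CTLA-4 replicate 4 (0.11), control IgG replicate 3 (0.12) or 4 (0.12). The mitochondrially encoded call ended without LDHA-KD anti-CTLA-4 replicate 5 (-0.13), LDHA-KD IgG replicate 2 (-0.20), control anti-CTLA-4 replicate 4 (-0.19) or 5 (-0.16), or control IgG replicate 4 (-0.16).

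The first pattern is the number of genes that differed between LDHA-KD and control tumours. Strongly outlying regions, as from copy number differences between the cell populations, are argued against as the source of most of them. Of the genes called under IgG, 10.6% lay in the 25 of 321 windows of 50 neighbouring genes with an outlying median (beyond 0.263). These windows held 7.54% of all genes placed in windows. Window medians had an SD of 0.153, against 0.0652 with genes permuted. Weaker regional differences, which this threshold cannot register, stay open. Depth is argued against too, since 5642 genes were called after thinning all libraries to equal depth. Of 100 splits of the samples, only 1, the real one, gave as many genes under IgG (5752, highest other 3098). The same held under anti-CTLA-4 (6711, highest other 3379). Chance is argued against in both, though 100 splits cannot exclude it. The knockdown stays open as the explanation and was not tested apart from other differences between the cell populations, because each condition has a single cell population.

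The second pattern is the higher level of immune cell lists in LDHA-KD tumours. A lower share of tumour cells that raised all other cells alike is argued against by the endothelial list. Its mean differed by -0.58 under IgG and -0.43 under anti-CTLA-4 (exact permutation, adjusted p = 0.0175 and 0.0201). The fibroblast and matrix list mean differed by 0.025 under anti-CTLA-4. A lower share of tumour cells as such stays open, since the epithelial tumour cell list was also lower and endothelial genes may have changed separately. That list is not a clean measure of the share, because its members did not fall alike. Epcam had -2.19 under IgG and -2.33 under anti-CTLA-4, while Cdh1 had -0.20 and -0.035 and did not pass (adjusted p = 0.117 and 0.789 with edgeR). Lymphoid tissue taken with the tumours is argued against as well, since the summed CPM of B cell genes went from 0.879 to 1.57 under IgG while that of T cell genes went from 6.40 to 24.99, a ratio of the rises of 0.0371, and the ratio was 0.0147 under anti-CTLA-4. More immune cells in LDHA-KD tumours may account for the pattern, as a hypothesis from the same data, and more transcripts per immune cell stays open and was not tested.

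The third pattern is the shift of lists with anti-CTLA-4 where no single gene passed edgeR's test. Mammary gland tissue as the cause of the T cell shift is argued against, since the T cell median was 0.87 in control and 0.51 in LDHA-KD tumours with the mean of the mammary gland list as a covariate. The 4 libraries apart on the second component are argued against as its whole cause, since the T cell median was 0.68 and 0.40 without them, while the adipocyte and mammary gland calls in control tumours were lost. With 0 genes called in control tumours, in LDHA-KD tumours and for the interaction, each of the 100 splits gives at least as many (100 of 100 in each, highest other 1537, 1 and 1), so the splits say nothing about chance here (edgeR had 1346, 1987 and 415 genes at an unadjusted p under 0.05, DESeq2 called 13, 49 and 0, and limma voom 0, 1479 and 0). The 1537 genes came from a split that exchanged control anti-CTLA-4 replicate 2 with control IgG replicate 1, which points to a structure of the samples, and exchanged labels of these libraries, which would change what the 0 genes mean, stay open, as their T cell list means (1.64 and 0.14) run the way the labels say while their hypoxia response means (6.77 and 7.26) run the other way.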

How the results depend on the processing

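Leaving out the 4 libraries apart on the second component, the mammary gland covariate, thinning to equal depth and the exact permutation of lists were chosen only after the results were seen. Under RLE size factors, no filter and thinning, all 134 gene values kept their direction and side of the threshold, and under the stricter filter 132 with a value did. With DESeq2, 127 did and 7 passed that had not, and with limma voom 114 did, 19 passed and 1 reversed. Of 84 list calls, 82 were kept with RLE size factors and 59 without the 4 libraries. Where no reason is given below, the cause was not tested.

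For anti-CTLA-4 in control tumours DESeq2 called 11 genes higher and 2 lower, and in LDHA-KD tumours 43 higher and 6 lower. In LDHA-KD tumours limma voom called 930 higher and 549 lower. Without the 4 libraries, and so with fewer samples, 2131 genes were higher and 2177 lower in LDHA-KD tumours under anti-CTLA-4, and 467 genes for treatment in control tumours, 368 in LDHA-KD tumours and 160 for the interaction had an unadjusted p under 0.05 with 0 called by edgeR. With each library left out in turn, the genes higher with anti-CTLA-4 in LDHA-KD tumours ranged from 0 to 1. With the replicate number as a block, 2943 genes were higher and 2998 lower in LDHA-KD tumours under IgG and 3570 and 3574 under anti-CTLA-4. For anti-CTLA-4 the block left 0 genes called, with 2504 at an unadjusted p under 0.05 in control and 2341 in LDHA-KD tumours (edgeR).

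With an estimated correlation, which widens the test by construction, 0 lists were higher and 0 lower in every contrast. The exact permutation test called 0 higher and 0 lower for anti-CTLA-4 in control and in LDHA-KD tumours, where it could not pass a list on its own. Lists higher in the interaction numbered 1 with the replicate block and 1 without the 4 libraries. Without the 4, lists lower in LDHA-KD tumours under anti-CTLA-4 numbered 10 and lists higher with treatment in LDHA-KD tumours 9. With each library left out, lists lower with treatment in LDHA-KD tumours ranged from 3 to 6, lists higher in the interaction from 1 to 5 and lists lower from 5 to 11.

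The correlation across genes of the anti-CTLA-4 effects, which are not independent replicates, was 0.569 with the stricter filter, 0.522 with the block, 0.530 with only the groups compared, 0.273 with limma voom and 0.248 without the 4 libraries. That of the LDHA-KD effects was 0.904 with the stricter filter, 0.884 with only the groups compared, 0.787 with limma voom and 0.883 without the 4 libraries.

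Some values reversed, 2 of them those of lists that camera had called. In the interaction, Cd8a was -0.17 and Ctla4 -0.064 with the block, and Cd8a was -0.018 and Ifng 0.15 with the mammary gland covariate. Without the 4 libraries, the interaction was 0.11 for Ldhb, -0.059 for Foxp3, -0.42 for Cd8a, 0.10 for Ifng, -0.024 for Ctla4 and 0.037 for the mitochondrially encoded list (called at -0.23). Without them the effect of anti-CTLA-4 was 0.064 for Ldhb in LDHA-KD tumours and 0.062 for the skeletal muscle list in control tumours (called at -0.40). With limma voom Ldhb was 0.078 in control tumours. With each library left out, the interaction ranged from -0.29 to 0.28 for Cd8a, -0.17 to 0.16 for Ctla4, -0.040 to 0.37 for Foxp3, -0.37 to 0.53 for Ifng and -0.21 to 0.036 for Ldhb, and the treatment effect on Ldhb in control tumours from -0.18 to 0.030. Ifng and Cd8a had means of 0.627 and 0.823 CPM in control tumours with IgG, and their values kept their direction and side of the threshold after thinning to equal depth.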

Other observations

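The genes and ratios here, and their tests, were chosen only after the results were seen. Granzyme genes of cytotoxic lymphocytes differed in direction. Gzme was lower in LDHA-KD than in control tumours under IgG at -2.33 (SE 0.33, adjusted p = 2.67e-05), from 8.71 to 1.73 CPM, while Gzma was higher at 0.93 (SE 0.29, adjusted p = 0.0180). Gzmk had 0.0841 CPM in control tumours with IgG, at the floor of 3 counts, and 0.380 CPM in LDHA-KD tumours with IgG, so no fold is given for it. Under anti-CTLA-4, Gzmc was higher at 1.66 (SE 0.44), Gzmf at 2.63 (SE 0.65) and Gzmg at 2.91 (SE 0.67). Gzmd (adjusted p = 0.208 with edgeR) and Gzme at -0.76 (SE 0.30, adjusted p = 0.0533) did not pass. The LDHA-KD libraries varied widely, with 5.06 ± 4.56 CPM of Gzmf and 5.44 ± 4.98 CPM of Gzmg, against 0.818 and 0.726 CPM in control tumours. Under IgG, Gzmc, Gzmf and Gzmg did not pass (adjusted p = 0.363, 0.545 and 0.357 with edgeR). The sequences of these paralogs are close, so reads may be shared between them, which was not tested. Cma1, a mast cell chymase gene, was higher in LDHA-KD tumours at 2.12 (SE 0.26) under IgG and 1.49 (SE 0.23) under anti-CTLA-4. Ptgs2, which encodes a prostaglandin synthase, was higher at 0.87 (SE 0.24) and 1.37 (SE 0.23). Krt14, a basal keratin gene, was lower at -1.63 (SE 0.29) and -1.40 (SE 0.28).

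One hypothesis was that Foxp3 rose with anti-CTLA-4 in LDHA-KD tumours beyond the T cell list. Foxp3 minus the T cell list mean differed by 0.077 on the log2 scale (exact permutation, two-sided p = 0.722), which leaves the hypothesis open, as the spread between libraries was wide. Another was that Cd8a fell relative to Foxp3, and the difference was -0.38 (exact permutation, two-sided p = 0.317), which also cannot be decided with these samples. Of the 16 tests of this kind, the smallest adjusted p was 0.317. The smallest unadjusted p was 0.0317, for Foxp3 minus the T cell list in LDHA-KD against control tumours under IgG at -0.51. Neither ratio measures Treg stability, since bulk counts do not follow single cells.

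In the regional test, 15 of the outlying windows under IgG were higher and 10 lower in LDHA-KD tumours, and the lowest spanned chromosome X from 5699727 to 10697364 with a median of -0.57. The next windows on chromosome X, up to 51681856, had -0.52 and -0.31. Adjacent windows on chromosome 2, from 23115606 to 32965345, had 0.33, 0.34, 0.32 and 0.36. Copy number differences there stay open and were not tested. Across the 321 windows the medians under IgG and under anti-CTLA-4 had a Pearson r of 0.925, and windows are not independent replicates. Foxp3 lies in that lowest window and was higher in LDHA-KD tumours.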
